A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

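RNA of 3 wild-type and 3 GCN4 deletion samples had been measured on Affymetrix arrays that carry probe sets for S. cerevisiae and for another yeast. Per the labels' protocols, total RNA was copied to cDNA and transcribed in vitro with biotin-labelled nucleotides. The submitters' processing notes name R 2.8.0, the affy package and RMA, with no role or order. The values deposited by the authors are normalised intensities on a linear scale, from 9.03 to 35044 over the arrays, 1 column per array. Log2 values had been assumed in the design, so log2 of each intensity was taken here, with no pseudocount because no value was 0 or below. Whether other arrays were normalised together with these 6 is not given in the sources used here. The median intensity over all probe sets was 245 to 259 on the wild-type arrays and 323 to 358 on the deletion arrays.

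Groups and replicate numbers came from the sample titles. Probe sets were named through the platform's annotation, and symbols were updated by gene identifier through the gene table of the R64 assembly, used here only for names and gene neighbours. Of the probe sets, 5498 named 1 S. cerevisiae gene, 1746 a gene of another species, 1 several genes and 3470 none. The 47 reporter and 166 control probe sets were not tested. For the 47 genes with more than 1 probe set, the one with the highest mean over all 6 arrays was used, which left 5449 genes. Of these, 117 were measured on probe sets that may match more than 1 gene. The background level of an array was taken from the other-species probe sets, as the 95th percentile. Where a gene was at or below it on all 3 arrays of a group, the other group's mean was set against the group's background level and given as "at least" a fold. Where this held on 1 or 2 of the 3 arrays, values below the level were set to it, and the number of arrays above it is given with the fold as "at least". The number of arrays limits the precision.

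Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, deletion minus wild-type, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 over 48 lists with at least 3 measured members, written from textbook knowledge before the data were examined and adjusted over the lists, beside camera with an estimated correlation and fry. Camera compares the test statistics of a list with those of the other genes, so its direction can oppose the sign of the list's median or mean log2 change, as in 12 lists. The reason was not worked out for each of these lists. On simulated data for this comparison with 5449 genes, limma recovered 86.6% of 67 genes changed by 0.5 on the log2 scale, 95.5% of 67 changed by 1 and 98.5% of 66 changed by 2, with 9 false among 196 calls. A planted list was recovered and 0 of 20 null lists were called. Genes were simulated independently and without replicate pairs, unlike the arrays here. The simulation therefore does not test how list calls hold where genes move together. Figures were drawn with matplotlib 3.10.9.

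The genes named follow a rule set before the data were examined. It took GCN4, the 10 lowest and 10 highest called genes whose groups did not overlap and whose higher group lay above the background level, up to 4 called members of each called list with the largest changes, up to 2 members of other lists, all members of the auxotrophy and mating-type lists, and 2 neighbours of GCN4 on each side. YEA6, although among the 10 lowest, is described with the neighbours. Other genes named were chosen after their values were seen.

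The replicate numbers were checked as pairs. Deviations from the group means correlated between same-numbered arrays of the 2 groups with r of 0.69, 0.53 and 0.71, all above the limit of 0.1 set beforehand, so the numbers were taken to pair the samples. Wild-type replicate 2 and deletion replicate 1, of different number, also lay above the limit with r of 0.23. The limit alone thus does not single out same-numbered arrays. The other pairs of different number between the groups had r of -0.64 to -0.17. Deviations from a group mean cancel out within the group. These negative values therefore follow in large part from the positive ones and are no separate evidence of pairing. The pairing is a hint from the data, since the labels give only numbers. The blocked fit is given where it changes a call. Alternatives covered normalization, centring, a filter on dim genes, the choice of probe sets, the test, array weights, the replicate block, a fold limit, and leaving out each array. Cyclic loess, with and without the block, leaving out both arrays numbered 3, scaling to the poly-A spike-ins, and leaving RPP1 out of the ribosomal protein list were added after the data were seen. The planned search for Gcn4 binding sites upstream of the called genes was not run, because genome sequence was not used here.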

Results

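The data were 6 Affymetrix expression arrays of the budding yeast Saccharomyces cerevisiae. Of these, 3 arrays measured the prototrophic laboratory strain FY4 (wild-type) and 3 measured a strain with GCN4 deleted. GCN4 encodes a basic leucine zipper activator of amino acid biosynthesis genes. Both strains were grown in minimal glucose medium and harvested in exponential phase, and the comparison asked how expression in the deletion strain differed from the reference. The deposited values were normalised intensities, analysed here as log2, for 5449 genes. The median intensity of these genes was 2112 to 2206 on the wild-type arrays and 2281 to 2341 on the deletion arrays. Between 97.2% and 98.8% of the genes lay above the background level of an array. Arrays of one group correlated across genes with r of 0.988 to 0.996, and arrays of different groups with r of 0.952 to 0.963 (genes are not independent replicates). The labels give neither the parent from which the deletion strain was made nor the ends of the deleted segment, so each change is a difference between these strains. They also do not say whether the replicates were separate cultures, so p-values measure only the spread between these arrays.

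GCN4 (YEL009C) was at the background level in the deletion strain. Its intensity was 23339, 18826 and 20142 on the wild-type arrays and 18.5, 22.3 and 18.1 on the deletion arrays. The level was therefore at least 283-fold lower in the deletion (adjusted p = 2.94e-07, limma). MIT1 (YEL007W), which encodes a transcription factor of pseudohyphal growth, was also at the background level in the deletion. It is the nearest measured gene on its side of GCN4, with the unmeasured YEL008W between them. Its log2 level was 11.82 ± 0.04 in the wild-type and 5.03 ± 0.30 in the deletion (SD, n = 3), at least 49.4-fold lower (adjusted p = 3.21e-06). The next measured gene, YEA6, a mitochondrial NAD+ carrier gene, fell 2.77-fold from 11.56 ± 0.05 to 10.09 ± 0.07 (adjusted p = 1.59e-05). On the other side of GCN4, GLC3, the glycogen branching enzyme gene, rose 1.46-fold (adjusted p = 0.0191), a call that ended on leaving out any array but wild-type replicate 2 (adjusted p of 0.0517 to 0.063). The call of GLC3 was kept in 10 of 18 alternatives, over which the highest adjusted p was 0.1. UBC8 had a log2 change of 0.20 and did not pass the test (adjusted p = 0.153), and passed with the replicate number as a block (adjusted p = 0.0291) or without wild-type replicate 2 (adjusted p = 0.0427). Farther out, VAC8 on that side fell 1.55-fold (adjusted p = 0.00183), and VAB2 on the side of MIT1 rose 1.38-fold (adjusted p = 0.00114).

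**Figure D1:**
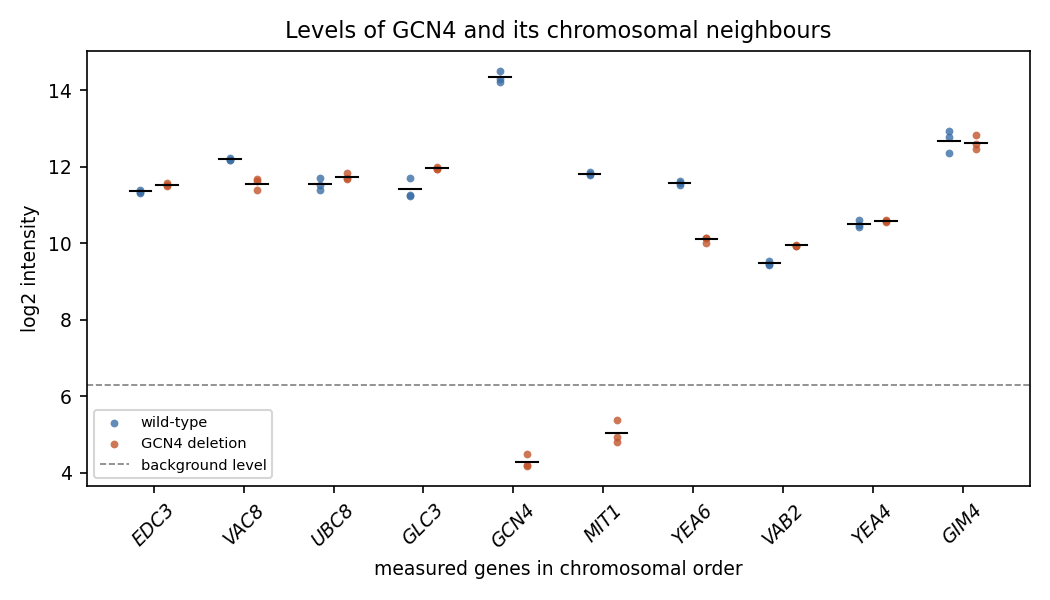
Log2 intensity of GCN4 and of the measured genes on either side of it, in chromosomal order, on each of 3 wild-type and 3 deletion arrays, with group means as short lines and the background level dashed. GCN4 and MIT1 lie under the background level on all 3 deletion arrays, and YEA6 has a log2 change of -1.47.

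Across the 5449 genes, 1756 changed at an adjusted p under 0.05, of which 418 were lower and 1338 higher in the deletion. Changes of at least 2-fold were found for 26 of the lower and 196 of the higher genes. After GCN4 and MIT1, the lowest gene was SUL1, a high-affinity sulfate permease gene, which fell 14.6-fold from a log2 level of 13.32 ± 0.03 to 9.44 ± 0.37 (SD, n = 3, adjusted p = 2.97e-05). DAL80, a GATA-type repressor of nitrogen genes, fell 8.78-fold (adjusted p = 5.38e-06), and FET4, a low-affinity iron transporter gene, fell 4.78-fold (adjusted p = 5.38e-06). The aquaporin gene AQY1 fell 3.35-fold, the meiotic regulator IME1 2.82-fold, the allantoate permease gene DAL5 2.8-fold and DAL7, a malate synthase of allantoin use, 2.72-fold. The share of calls that were higher depended on scaling. It was 76.2% as deposited, 52.5% (778 higher, 703 lower) after each array was centred on its median, which shifted the median change by -0.10, and 44.2% (692 higher, 873 lower) after quantile normalization, which shifted it by -0.11. With the replicate number as a block, 666 genes were lower and 1925 higher, and the share of higher calls was 74.3%.

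Among the 10 highest genes by the naming rule, PRM6, a pheromone-regulated membrane protein gene, was at the background level in the wild-type and at least 17.8-fold higher in the deletion (adjusted p = 3.21e-06). FLO1, a flocculin gene with similar family members that its probes may share, rose 23.7-fold from a log2 level of 7.93 to 12.50, with a standard error of the difference of 0.10. FIG1, needed for calcium entry during mating and above the background level on 2 of 3 wild-type arrays, rose at least 20.1-fold, and PRM7, another pheromone-regulated gene, 10.7-fold. BSC1 rose 17.5-fold, YAP6, a basic leucine zipper transcription factor gene, 14-fold, YAL064W 13.4-fold, and NCA3 10.3-fold. YGP1, a secreted glycoprotein gene induced by nutrient limitation, rose 13.3-fold, and SIP18, above the background level on 1 of 3 wild-type arrays, rose at least 8.77-fold. The adjusted p of these 10 genes lay between 3.21e-06 and 0.000617.

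**Figure D2:**
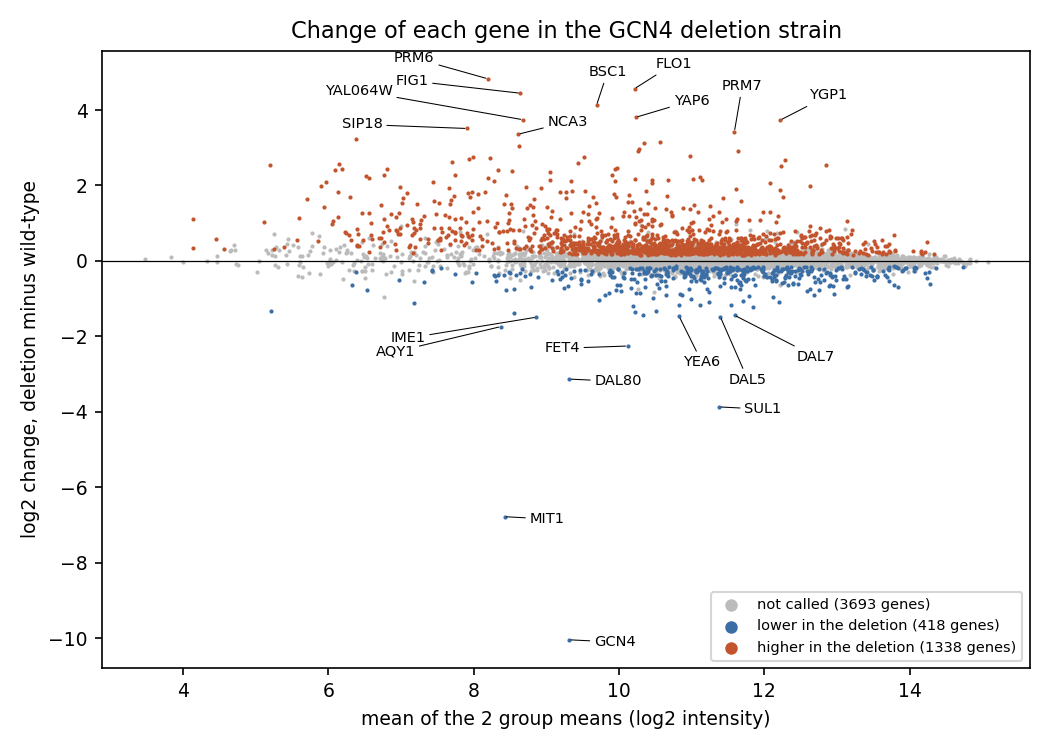
Log2 change of each of 5449 genes (deletion minus wild-type) against the mean of both group means in log2 intensity. Blue points are the 418 lower genes, red points the 1338 higher genes and grey points the genes not called, and the 10 lowest and 10 highest genes by the naming rule are labelled.

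Over 9 lists of amino acid biosynthesis genes fixed beforehand, 42 of 99 measured genes fell, 3 rose and 54 did not pass the test, with a median log2 change of -0.15. After centring 61 fell, 1 rose and 37 did not pass, and after quantile normalization 44 fell and 1 rose. The 9 lists were tested separately and not as a whole. Only SUL1 among them fell by at least 2-fold. In arginine biosynthesis 5 of 8 genes fell (5 adjusted over the list alone), among them ARG7 by 1.95-fold, ARG4 by 1.83-fold and ARG1, argininosuccinate synthetase, by 1.32-fold (adjusted p = 4.29e-05 by camera, adjusted p = 0.268 with an estimated correlation). In histidine biosynthesis 5 of 7 genes fell (6 adjusted over the list alone), including HIS5 by 1.54-fold and HIS4 by 1.44-fold (adjusted p = 8.69e-06, adjusted p = 0.129 with an estimated correlation). In branched-chain amino acid biosynthesis 7 of 12 genes fell (8 adjusted over the list alone), led by LEU9 at 1.62-fold and LEU2 at 1.35-fold (adjusted p = 5.47e-07, adjusted p = 0.227 with an estimated correlation). Serine, glycine and one-carbon genes also fell in 7 of 12 cases (10 adjusted over the list alone), or in 11 after centring, including SER3 by 1.56-fold and GCV2, a glycine cleavage subunit, by 1.4-fold (adjusted p = 1.74e-06, adjusted p = 0.129 with an estimated correlation).

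Aromatic amino acid genes moved in both directions, with 7 of 13 lower and 2 higher (7 and 2 adjusted over the list alone). ARO3 fell 1.68-fold and ARO1 1.62-fold, whereas ARO9, an aromatic aminotransferase gene used in catabolism and above the background level on 1 of 3 wild-type arrays, rose at least 1.39-fold, a call lost after quantile normalization (log2 change 0.12, adjusted p = 0.395). The list was lower at adjusted p = 0.000104, with adjusted p = 0.268 with an estimated correlation. In homoserine and threonine biosynthesis HOM3, aspartate kinase, fell 1.58-fold and HOM2 1.21-fold, and 3 of 5 genes did not pass (2 lower adjusted over the list alone, adjusted p = 0.00305, adjusted p = 0.289 with an estimated correlation). That list was not called after quantile normalization (adjusted p = 0.0621). Of 13 genes for glutamate, glutamine, aspartate, asparagine, alanine and proline, 5 fell and 1 rose (5 and 1 adjusted over the list alone), or 9 fell and 0 rose after centring by limma. GDH3 was 1.42-fold lower and ASN1 1.21-fold higher, the latter not after centring (adjusted p = 0.131) or with all non-control probe sets in the fit (adjusted p = 0.0547). The list was lower at adjusted p = 0.000232, with adjusted p = 0.268 with an estimated correlation. Among sulfate assimilation and methionine genes, MET13 and MET22 fell beside SUL1, by 1.51-fold and 1.34-fold, and 18 of 21 members did not pass (3 lower adjusted over the list alone and 7 lower after centring, adjusted p = 0.00184, adjusted p = 0.141 with an estimated correlation). That list was not called after quantile normalization (adjusted p = 0.0866) or with all non-control probe sets in the fit (adjusted p = 0.0554). In lysine biosynthesis 1 of 8 genes, LYS20, fell, by 1.20-fold, and 0 did so adjusted over the list alone, with the other members between -0.16 and 0.22 on the log2 scale (adjusted p = 0.0421, adjusted p = 0.502 with an estimated correlation). That call was lost in 9 of 19 alternatives (adjusted p of 0.0733 to 0.264), among them centring, quantile normalization (adjusted p = 0.264), and leaving out wild-type replicate 3 (adjusted p = 0.144), deletion replicate 1 (adjusted p = 0.105) or deletion replicate 2 (adjusted p = 0.0938). LYS20 itself lost its call after quantile normalization (adjusted p = 0.069) and on leaving out any array but deletion replicate 3 (adjusted p of 0.0851 to 0.135), and 2 genes of the list were lower after centring.

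Known Gcn4 targets outside amino acid synthesis fell in 6 of 8 cases (6 adjusted over the list alone). PCL5, a cyclin that promotes Gcn4 turnover, fell 2.54-fold (adjusted p = 2.19e-05), TMT1 1.66-fold, and ATR1, a multidrug transporter gene, 1.31-fold. The list was lower at adjusted p = 4.71e-06, with adjusted p = 0.129 with an estimated correlation. Purine biosynthesis genes fell in 5 of 13 cases (9 adjusted over the list alone), or in 9 after centring, among them ADE12 by 1.19-fold and IMD2, measured on a probe set shared with similar genes, by 1.47-fold (adjusted p = 9.5e-05, adjusted p = 0.289 with an estimated correlation).

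Genes under nitrogen catabolite repression were mostly lower, with 14 of 21 lower and 4 higher (15 and 5 adjusted over the list alone). DAL80, DAL5, DAL7 and DAL3 fell 8.78-fold, 2.8-fold, 2.72-fold and 2.24-fold. The list was lower at adjusted p = 4.12e-08, with adjusted p = 0.129 with an estimated correlation. Amino acid permease genes split, with 10 of 17 higher and 5 lower (11 and 5 adjusted over the list alone). GAP1 and PUT4, which were lower, are in this list and in the nitrogen catabolite repression list. AGP1, a broad-range permease gene, rose 6.93-fold from a log2 level of 9.59 to 12.38, MUP1, a methionine permease gene, 3.68-fold, and ALP1 3.28-fold. BAP2, above the background level on 1 of 3 wild-type arrays, rose at least 4.05-fold. As a list the permeases were higher at adjusted p = 0.0421, with adjusted p = 0.289 with an estimated correlation and 0.15 with the replicate number as a block. Leaving out wild-type replicate 2 gave an adjusted p of 0.0873 and leaving out deletion replicate 3 gave 0.0502, array weights gave 0.0698, and leaving out both arrays numbered 3 gave 0.0621.

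Genes of respiration were higher. Of 30 respiratory chain and ATP synthase genes 23 rose (28 adjusted over the list alone), with a median fold of 1.4 and examples in CYC1, cytochrome c, at 2.05-fold and QCR6 at 1.67-fold (adjusted p = 1.89e-06, adjusted p = 0.289 with an estimated correlation). In the tricarboxylic acid cycle 11 of 16 genes rose and 1 fell (11 and 1 adjusted over the list alone), or 7 rose after centring, including the succinate dehydrogenase genes SDH2 at 1.73-fold and SDH1 at 1.62-fold (adjusted p = 0.00953, adjusted p = 0.469 with an estimated correlation). Genes of fermentation, acetate and glycerol metabolism were lower in 6 of 14 cases and higher in 1 (6 and 1 adjusted over the list alone), with ADH5 falling 2.33-fold, GPD2 2.13-fold and ALD5 1.75-fold (adjusted p = 0.00031, adjusted p = 0.129 with an estimated correlation). In glycolysis 3 of 16 genes fell (1 adjusted over the list alone), or 6 after centring, among them ENO1, enolase, by 1.22-fold (adjusted p = 0.000426, adjusted p = 0.338 with an estimated correlation). The glycolysis call was lost after quantile normalization (adjusted p = 0.335) and after cyclic loess (adjusted p = 0.0836).

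General stress response genes rose in 28 of 30 cases (28 adjusted over the list alone), with a median fold of 2.16. YGP1, DDR2, the small heat shock protein gene HSP26 and the membrane-protecting protein gene HSP12 rose 13.3-fold, 7.57-fold, 5.71-fold and 6.42-fold. The list was higher at adjusted p = 2.49e-10, with adjusted p = 0.313 with an estimated correlation. Heat shock chaperone genes rose in 12 of 18 cases (12 adjusted over the list alone), led by SSA4 at 3.16-fold and HSP82, an Hsp90 gene, at 1.91-fold (adjusted p = 0.00024, adjusted p = 0.313 with an estimated correlation). HSP104 is in both lists.

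Haploid and pheromone response genes rose in 13 of 13 cases (13 adjusted over the list alone), or in 11 after centring, with a median fold of 1.68. FIG1 rose at least 20.1-fold, PRM1, which acts in cell fusion, 4.81-fold, the agglutinin anchor gene AGA1 3.97-fold and FIG2 3.76-fold. The list was higher at adjusted p = 3.14e-08, with adjusted p = 0.227 with an estimated correlation. STE2, the receptor of a cells, had a log2 level of 14.05 in the wild-type and 14.26 in the deletion. STE3, the receptor of alpha cells, had 7.57 in the wild-type and 7.30 in the deletion. Of 7 a-specific genes 3 rose (4 adjusted over the list alone), namely ASG7 by 4.46-fold, BAR1, a protease that degrades alpha factor, by 1.65-fold and STE2 by 1.16-fold (adjusted p = 0.0343, adjusted p = 0.268 with an estimated correlation). The pheromone genes MFA1 and MFA2, the transporter gene STE6 and AGA2 had log2 changes of 0.84, 0.44, 0.18 and 0.79 that did not pass, and passed with the replicate number as a block (adjusted p of 0.000821, 0.0376, 0.0181 and 0.00251). Of 4 alpha-specific genes MF(ALPHA)1 and SAG1 rose and MF(ALPHA)2 and STE3 fell (2 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.487). MF(ALPHA)1 was at the background level in the wild-type and at least 1.13-fold higher in the deletion. Its call was kept in 11 of 18 alternatives, and lost among others after quantile normalization (adjusted p = 0.141) and cyclic loess (adjusted p = 0.0937). MF(ALPHA)2 and STE3 had log2 changes of -0.57 and -0.27. Other-species probe sets within 0.5 of the same mean level, 10 and 20 in number, had medians of -0.36 and -0.32. The call of STE2 ended after centring (adjusted p = 0.292), with all non-control probe sets in the fit (adjusted p = 0.103) and on leaving out any array but wild-type replicate 3 (adjusted p of 0.0658 to 0.0954), and that of MF(ALPHA)1 without deletion replicate 1 or 2 (adjusted p of 0.0672 and 0.071).

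The list of cytosolic ribosomal proteins held 128 genes, 1 of which, RPP1, encodes a subunit of RNase P and was taken in by its name. Of the 127 others, as of all 128, 0 were called by limma, with 2 at an unadjusted p under 0.05, 5 called with the replicate number as a block, 2 lower after centring and 0 adjusted over the list alone. Their median log2 change was 0.01, yet camera placed the list lower than other genes (adjusted p = 0.0145, adjusted p = 0.648 with an estimated correlation, and adjusted p = 0.0166 and 0.655 without RPP1). That call was lost in 7 of 20 alternatives (adjusted p of 0.0671 to 0.956), among them quantile normalization (adjusted p = 0.361) and leaving out wild-type replicate 2 (adjusted p = 0.0671) or deletion replicate 3 (adjusted p = 0.213). Mitochondrial ribosomal protein genes rose in 19 of 66 cases (19 adjusted over the list alone), or in 5 after centring and 9 after quantile normalization, with RSM22 at 1.37-fold and MRP51 at 1.33-fold (adjusted p = 0.022, adjusted p = 0.648 with an estimated correlation). That call was lost without wild-type replicate 3 (adjusted p = 0.206) or deletion replicate 2 (adjusted p = 0.132). Of all 5449 genes, 1338 were called higher, 778 after centring and 692 after quantile normalization. The share of this list that rose was therefore close to that of all genes, and smaller after centring. The mean log2 change of the list minus that of other genes was 0.06, and -0.01 without wild-type replicate 3. Of 18 cytosolic aminoacyl-tRNA synthetase genes only ILS1 passed, 1.23-fold lower (1 adjusted over the list alone, adjusted p = 0.0241, adjusted p = 0.672 with an estimated correlation), and 3 were lower after centring. The call of the list was lost in 8 of 19 alternatives (adjusted p of 0.0671 to 0.476). These were quantile normalization (adjusted p = 0.361), all non-control probe sets in the fit (adjusted p = 0.316), cyclic loess (adjusted p = 0.204), cyclic loess with the replicate number as a block (adjusted p = 0.22), fry (adjusted p = 0.476), and leaving out wild-type replicate 3 (adjusted p = 0.0965), deletion replicate 1 (adjusted p = 0.116) or deletion replicate 2 (adjusted p = 0.0671).

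**Figure D3:**
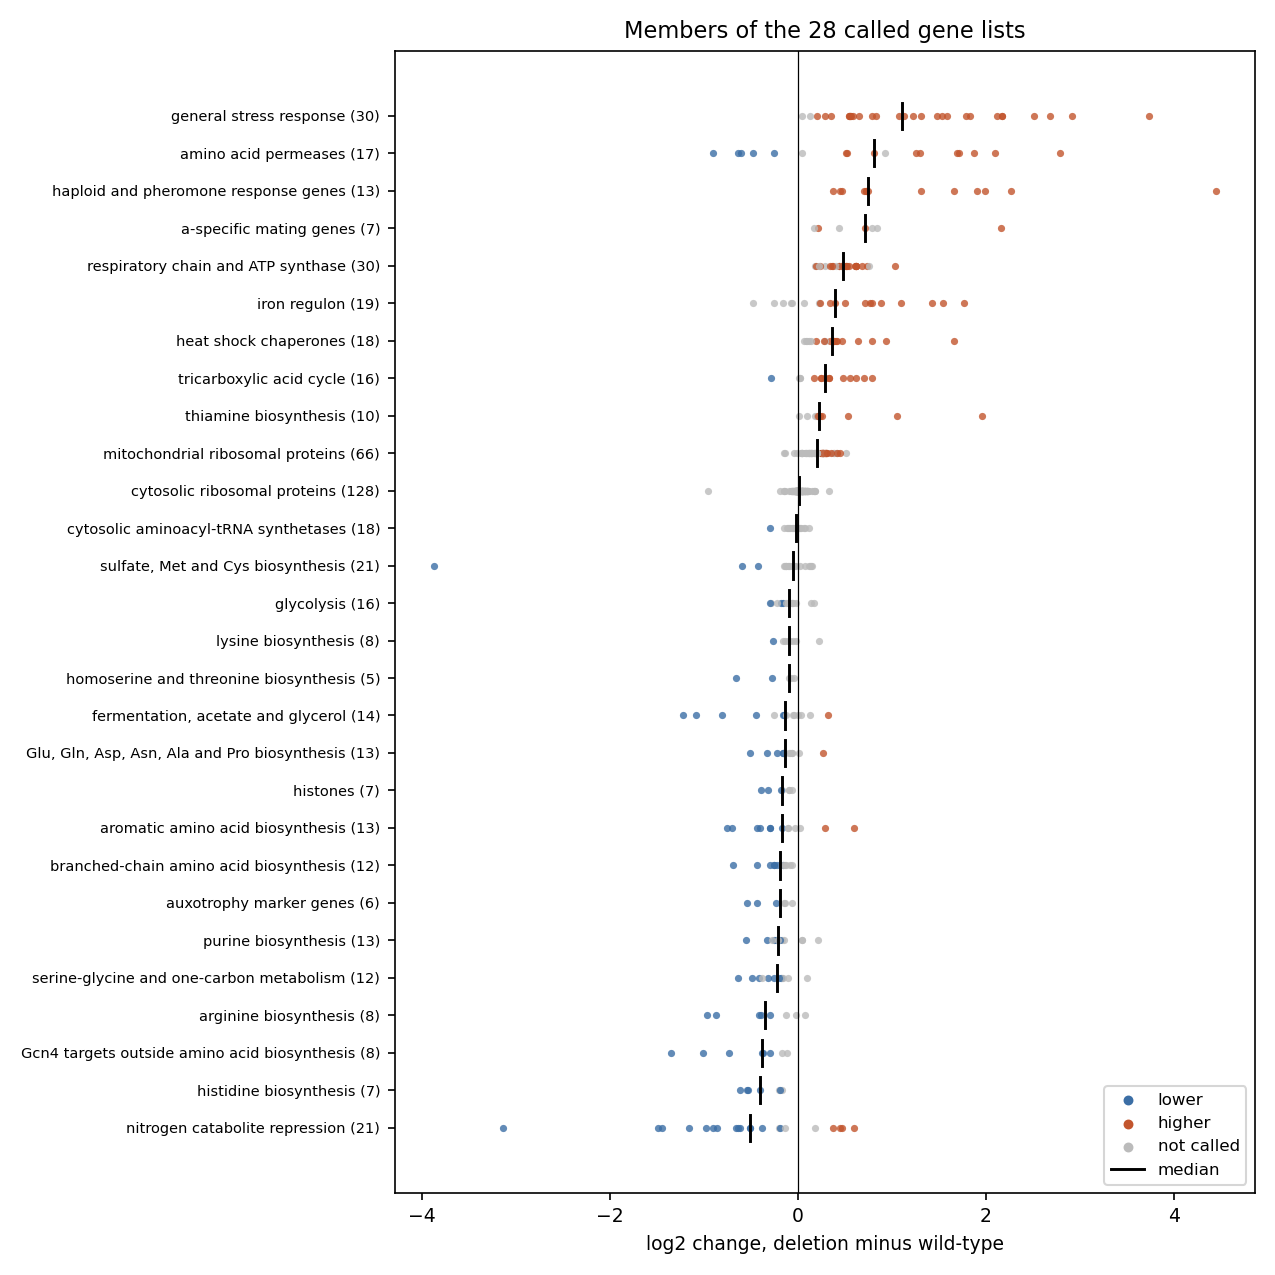
Log2 change (deletion minus wild-type) of the members of the 28 called lists, 1 row per list with the number of measured genes in brackets, blue for lower, red for higher and grey for genes not called, with list medians as black bars. The general stress list has a median of 1.11 and the nitrogen catabolite repression list a median of -0.51.

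Genes commonly used as auxotrophy markers were expressed in both strains. URA3, LEU2, HIS3, MET17, LYS2 and ADE2 had mean log2 levels of 12.65, 13.90, 12.44, 14.37, 13.27 and 13.49 in the wild-type and 12.58, 13.47, 11.90, 14.22, 13.14 and 13.26 in the deletion. LEU2, HIS3 and ADE2 fell by 0.43, 0.54 and 0.23 on the log2 scale (4 of 6 lower adjusted over the list alone, adjusted p = 0.00031, adjusted p = 0.129 with an estimated correlation). All 6 genes are also in lists of amino acid, purine or pyrimidine biosynthesis, so this call is not separate from those lists. MET17, with a change of -0.15, did not pass (adjusted p = 0.0688), and passed with the replicate number as a block (adjusted p = 0.0433), after centring (adjusted p = 0.03), with array weights (adjusted p = 0.0394) and with a trended and robust variance (adjusted p = 0.0296). After centring 5 of 6 genes were lower. Across all 48 lists, 28 were called by camera, 10 higher and 18 lower. Some lists share members, with 18 measured memberships repeated between lists, so the calls are not independent. With an estimated correlation 0 were called, 9 having an unadjusted p under 0.05, and fry, which tests only whether a list's genes move on balance one way, called 33 and kept 24 of the 28.

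The 36 poly-A spike-in probe sets had mean log2 levels of 8.22 ± 0.41 in the wild-type and 9.82 ± 0.27 in the deletion (SD, n = 3), with a median difference of 1.61. The 27 hybridisation controls had a median difference of -0.29, the 8 probe sets for 25S ribosomal RNA -0.38, the 8 for 18S ribosomal RNA 0.12 and the 6 for ACT1 -0.02. No processing date was used here, so a batch that followed the groups cannot be told apart from the deletion.

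**Figure D4:**
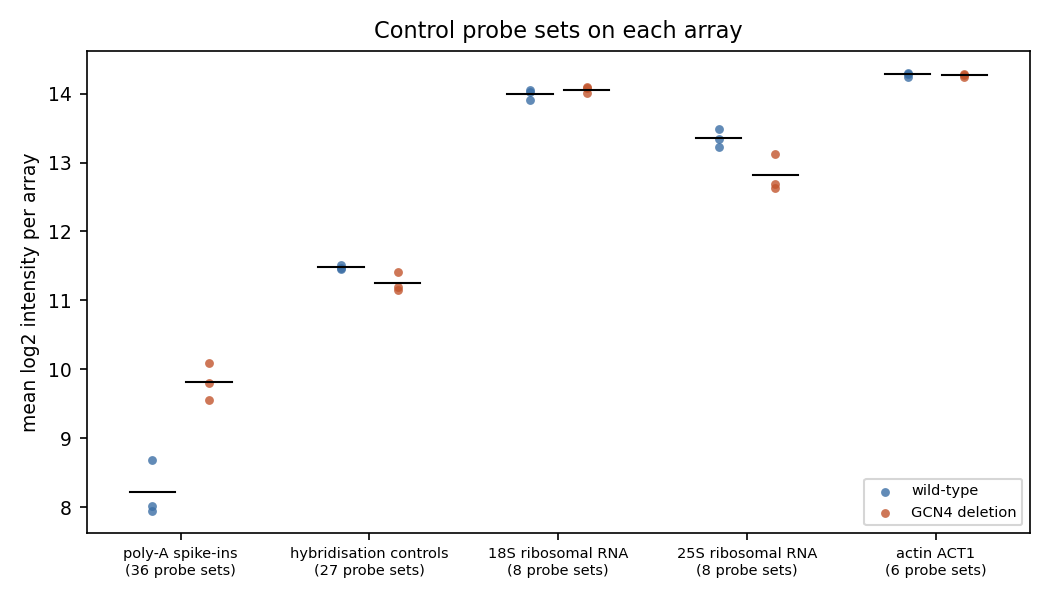
Mean log2 intensity of 5 families of control probe sets on each of 3 wild-type and 3 deletion arrays, with group means as short lines. The poly-A spike-ins have a mean of 8.22 in the wild-type and 9.82 in the deletion, and ACT1 lies at 14.28 and 14.27.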

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

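The tests of the spike-ins, of the other-species probe sets and of centring were chosen after the results were seen, and cyclic loess was an alternative added after seeing the data.

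A reporter probe set, which matches a sequence outside the yeast genome's own genes, had a mean log2 level of 4.64 ± 0.17 on the wild-type arrays and 14.26 ± 0.01 on the deletion arrays (SD, n = 3), a difference of 9.62 and at least 223-fold. It stood out as a signal in data that the comparison of genes did not use, and was the only 1 of 47 reporter probe sets higher by at least 2-fold. Another reporter probe set named for the same sequence did not share the rise. It was at the background level in the wild-type, with log2 levels of 6.25 ± 0.15 there and 5.89 ± 0.10 in the deletion. Among the 3470 unnamed probe sets, 8 were higher and 3 lower by at least 2-fold, and the brightest of the higher ones rose from a log2 level of 11.11 to 14.05.

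The poly-A spike-in controls, also outside the comparison of genes, were higher in the deletion by a median of 1.61 on the log2 scale, while more genes were called higher than lower. A single trend with intensity shared by all probe sets is argued against: 148 other-species probe sets at a mean log2 level of 6 to 8 had a median change of -0.26, with a 75th percentile of -0.12, where 253 S. cerevisiae genes of the same level had a median of 0.39. A common shift of all S. cerevisiae genes, or a trend with level among them, cannot be told apart from a real rise: 52.5% of calls were higher after centring and 55.7% after cyclic loess, but both bring the typical change to about 0 by construction. The mean spike-in level differed by 4.61 SDs of arrays within a group (SD 0.35), and different amounts of spike-in or of RNA, or a processing batch, cannot be told apart from a change in messenger RNA content, because each follows the groups. The deletion's own effect on the total stays open and was not tested.

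The real split of the 6 arrays gave 1756 changed genes. It was 1 of 10 splits, too few for a share under 0.05, and the highest count of any other split was 0 by limma, with 3 to 383 genes at an unadjusted p under 0.05. Of the splits, 4 part all 3 same-numbered pairs, the real one included, and the other 6 part 1 pair and keep both other pairs together.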

How the results depend on the processing

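Cyclic loess, leaving out both arrays numbered 3, leaving out RPP1, and spike-in scaling were chosen after seeing the data, and the cause of the changes below was not tested unless stated. GCN4 was lower in the 19 alternatives run for it. With the deletion arrays set at the background level its log2 change was -8.06 or lower in the 12 that move values. With all non-control probe sets in the fit, which changes both the moderated variances and the number of tests adjusted over, 1061 genes changed (229 lower, 832 higher). A fold limit of 2, stricter by construction, left 222 (26 lower, 196 higher). Quantile normalization gave 873 lower and 692 higher, centring 703 and 778, and cyclic loess 690 and 868. Scaling to the spike-ins gave 5283 changed, 5242 lower and 41 higher, because it lowers the median change by construction to -1.52, and 92 of the 1338 higher genes stayed above 0. The replicate block gave 2591 changed (666 lower, 1925 higher), and with cyclic loess 1209 lower and 1326 higher. Calls shared with the values as deposited numbered 1756 with the block, 1196 after centring, 1103 after quantile normalization and 1284 after cyclic loess. Without 1 array, 1190 to 1496 genes changed, 270 to 355 were lower and 920 to 1141 higher, with fewer arrays in each fit. Wild-type replicate 1 and deletion replicate 2 moved the lower count most, to 270 and 272. Without both arrays numbered 3, 1407 genes changed.

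Called lists numbered 28, 21 after quantile normalization, 25 to 28 without 1 array, 33 by fry and 0 with an estimated correlation. The direction of the cytosolic ribosomal protein list turned to higher, without a call, in some alternatives. These were quantile normalization (shift 0.0095, adjusted p = 0.361 by camera) and fry (mean 0.011, adjusted p = 0.872). Cyclic loess with or without the block did the same (adjusted p of 0.429 and 0.799 by camera), where its test was higher although its mean shift was -0.029. Fry does not compare a list with other genes. By it, gluconeogenesis genes (mean 0.19), hexose transporters (mean 0.25) and phosphate genes (mean 0.14) were higher. Their mean log2 change minus that of other genes was 0.05, 0.11 and -0.0003, and camera did not call these lists. The median of the hexose transporters was -0.16. Beyond those named in the report and here, the block changed the call of no list, and among the named genes it added calls only. Of 141 named genes called, 20 lost the call without 1 array (adjusted p up to 0.143). No direction of a named gene turned in the alternatives run for it. Spike-in scaling, which put most of the higher genes below 0, was run for GCN4 only among the named genes and is not covered. The unmoderated test ended the calls of 14 named genes, among them CYC1 (adjusted p = 0.0525), HIS3 (0.0505) and GLC3 (0.0693). A trended and robust variance ended that of STE3 (0.0548). With all non-control probe sets 23 calls ended, among them that of ADE2 (0.0553), and after quantile normalization 16 ended. Of 154 named genes other than GCN4, 109 kept their outcome, called or not, in every alternative run for them. The mean correlation within groups was 0.992, and 0.991 to 0.992 in its alternatives. The Gcn4 site search was not run, with its alternatives of other upstream lengths, a fold limit and a control motif. Signal over background limits the 56 genes below the background level on all 6 arrays.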

Other observations

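The test of MIT1 over the alternatives and the random lists were set out before their results were seen. The use of the background level in the test of MIT1, and the tests of YEA6 and of the alpha-specific genes, were chosen after theirs were seen.

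Iron regulon genes rose in 12 of 19 cases (12 higher and 1 lower adjusted over the list alone). FIT2, a cell wall mannoprotein gene of siderophore retention, rose 3.40-fold, the siderophore transporter gene SIT1 2.93-fold, and the heme oxygenase gene HMX1 2.68-fold (adjusted p = 0.0127 by camera, adjusted p = 0.289 with an estimated correlation). Thiamine biosynthesis genes rose in 7 of 10 cases (7 adjusted over the list alone), or in 2 after centring, with PHO3, thiamine-repressible phosphatase, 2.08-fold higher and THI13, on a probe set shared with close copies, 3.89-fold higher (adjusted p = 0.0127, adjusted p = 0.313 with an estimated correlation). That list was not called after quantile normalization (adjusted p = 0.0621). Histone genes fell in 3 of 7 cases (3 adjusted over the list alone), with HTB2 1.25-fold lower (adjusted p = 0.00361, adjusted p = 0.475 with an estimated correlation), and were not called after quantile normalization (adjusted p = 0.0866) or by fry (adjusted p = 0.107).

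Of the 20 lists that camera did not call, several held strongly changed members. In the pentose phosphate pathway 4 of 11 genes rose (4 adjusted over the list alone), TKL2 6.63-fold and GND2 4.58-fold, both second copies of a more abundant enzyme, and the list had an adjusted p of 0.0613. It was called higher in 6 of 19 alternatives (adjusted p of 0.00014 to 0.0496), quantile normalization among them (adjusted p = 0.00729). HXT5 and HXT8, hexose transporter genes with similar family members, rose 5.31-fold and at least 2.64-fold, HXT8 being above the background level on 2 of 3 wild-type arrays. In all, 3 of 10 hexose transporter genes rose and 2 fell (3 and 3 adjusted over the list alone), HXT1 by 1.55-fold and HXT4 by 1.27-fold, with a median log2 change of -0.16. POT1, the peroxisomal thiolase gene, was at the background level in the wild-type and at least 2.72-fold higher in the deletion. INO1, inositol phosphate synthase, rose 2.37-fold, and OYE3 2.87-fold. Of the meiotic genes, HOP1, above the background level on 1 of 3 wild-type arrays, rose at least 2.60-fold and IME1 fell 2.82-fold. SNZ3, on a shared probe set, rose 1.52-fold, and BIO3 1.56-fold.

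MIT1 and YEA6, near GCN4 on the chromosome, were lower in the deletion. The log2 change of MIT1 nearest 0 over 12 alternatives was -5.55 with the deletion arrays set at the background level. Under those that rescale the arrays it was -5.73 to -7.23, so no scaling tried removed the fall. These scalings shifted the median change of all genes by only -0.08 to -1.60. None could have brought MIT1 near 0, so the test over the alternatives could not decide on scaling. A scaling shared by all genes would move the typical gene as far as MIT1 and YEA6. The median log2 change of all genes was 0.09 and that of YEA6 was -1.47, which argues against such a scaling for both genes. An effect of the deletion on the chromosome around GCN4, loss of MIT1 itself included, may underlie the lower MIT1 and YEA6, as the ends of the deleted segment were not given in the labels. Only 0.165% of genes, 9 in all, changed as low as YEA6, but YEA6 is itself part of the pattern, and of 7 other measured neighbours 1 was lower and 3 were higher. This cannot be told apart from an effect of losing Gcn4, because every deletion array carries both.

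Mating and pheromone genes were higher in the deletion. Of 10000 random lists matched on mean level, 0% had a median as high as 0.75, and the highest had 0.37. Genes of this level therefore did not in general rise as far. The list was chosen because it was higher in these data, and random genes need not move together as its members may. The 0% is therefore no measure of significance, and the list had an adjusted p of 0.227 by camera with an estimated correlation. A share of alpha cells in the deletion cultures cannot be told apart from other causes. Of the 4 alpha-specific genes, SAG1 rose, MF(ALPHA)1 was at least 1.13-fold higher, a call lost after quantile normalization (adjusted p = 0.141), and MF(ALPHA)2 and STE3 were called lower (log2 changes of -0.57 and -0.27). A share of alpha cells would raise all 4, but of those lower 0 lay more than 2 SE below the lower quartile of other-species probe sets of the same level (-0.50 and -0.51). These quartiles rest on only 10 and 20 probe sets, so the test is weak and decides nothing about alpha cells. A change tied to the loss of GCN4, or to another difference between the strains, stays open as a hypothesis and was not tested.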
